A study of Homo sapiens with 15 samples.

How the data were processed

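The series holds 15 RNA libraries of total RNA from 5 human cell lines in culture, 3 per line, with no treatment given in the sample labels. Per the labels' protocols, RNA was extracted with TRIZOL and libraries were made with a stranded total RNA kit and a ribosomal RNA removal kit. The deposited files give an expected count per gene, a TPM and an FPKM value and an effective length for 27968 gene symbols. The expected counts are estimates that need not be whole, made with RSEM per the submitters' processing notes, which also name the genome build hg19. The RSEM version, the aligner, the annotation and whether counting used strand are not given in the sources used here. RSEM divides reads that match several genes by an estimate, so genes with near-identical copies (the AKR1C, KRT8x, CST, MAGE, SPANX, MT1, histone and HLA families, KRT87P) and overlapping or antisense genes are uncertain. The deposited TPM and FPKM values were not used. No coordinates are given, because the reference at hand is of another build; it served only for GC content by symbol.

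Groups were taken from the cell line label, and replicate numbers from the sample titles. The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a text says that a choice came after. Expected counts were rounded to whole numbers. Genes passing edgeR's filterByExpr were kept, 17673 over the 15 libraries and 17536 over the line sums. Normalization used TMM factors, and the test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05 (R 4.3.3, edgeR 4.0.16). Every adjusted p of a gene comes from that test unless another is named. The 4 comparisons of 2 lines share a fit with 1 coefficient per line over all 15 libraries. Lung and breast were compared on counts summed over the 3 libraries of each line, because the tissue is a property of the line. A gene was called line-specific when it was at least 4-fold higher than in each of the other 4 lines with an adjusted p under 0.05 in all 4 contrasts.

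The 26 gene lists hold 612 entries, of which 13 have symbols absent from the files and 4 symbols are in more than 1 list. Each list with at least 5 tested members was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison. Adjusted p of a list comes from camera with its preset correlation unless an estimated correlation is named. The alternatives camera with an estimated correlation and fry were also run; fry tests whether the members move one way on balance and compares a list with no other genes. Higher and lower in a count of members mean called over all genes tested. A list median places genes with no counts in a group at their bound.

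Named genes follow a fixed rule. It takes, per comparison and direction, the 10 called genes with the largest fold change at 50 CPM or more whose libraries did not overlap between groups, and up to 2 called members per list and direction at 5 CPM or more. It adds 8 line-specific genes per line, at 50 CPM or more there, and 12 genes named in every line. Log2 fold changes are given with a standard error (SE) derived from the test. It is the absolute log2 fold change over the square root of the test's F statistic. This SE can be too small where a group has few counts. A gene with no counts in a group has a fold computed against a floor of 3 counts over that group, written as at least N-fold. A gene with 1 to 3 counts has a ratio with an exact 95% binomial interval, or its counts. Intervals and floors cover counting error only. Total expected counts of 16454000 to 52053000 per library set the precision, and floors over a line lay between 0.0215 and 0.0601 CPM.

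Replicates of a line were compared before they were averaged, and all pairs differed by more than sampling noise. Chi-square per degree of freedom ran from 2.6 to 122.9. For H23 replicate 1 it was 97.4 and 122.9 with replicates 2 and 3, which had 5.24 between them. For T47D replicate 3 it was 73.1 and 77.2 with replicates 1 and 2, which had 14.2 between them. In MCF-7-TNR it ran from 35.6 to 80.1. The steps were tested on simulated counts drawn from the real means and library sizes. Pairs of lines recovered 71% to 78% of genes changed 2-fold and 97% to 99% of those changed 4-fold, with 4.86% to 8.15% false among calls. Only 100 genes per fold were changed out of 17673, raised and lowered in equal number. Far more genes differed between the real lines, where normalization is less certain, so these rates need not hold there. The lung and breast test, simulated with the dispersion estimated for each gene, recovered 0% at 2-fold, 4-fold and 32-fold and 75.5% at 1024-fold. Its only calls in the run with 2-fold and 4-fold changes were 2 false ones, and at 1024-fold 7.36% of calls were false. The common dispersion was 1.07 between lines against 0.0278 between libraries. The line-specific rule recovered 99% of genes raised 8-fold.

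Alternatives covered DESeq2 size factors, upper-quartile factors, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, no filter or a stricter one of 10 counts in every library of a line, an effective length offset, leaving out genes above 1% of counts, leaving out each library in turn, a fit of 6 libraries, a replicate block, and for tissue a contrast over 15 libraries, the line as a random block and leaving out each line. RNA classes without a poly(A) tail were taken by symbol, 143 tested genes, and leaving them out was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.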

Results

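RNA was measured in 15 libraries from 5 human cancer cell lines, with 3 libraries per line. A549 and H23 are lung cancer lines. MDA-MB-231 and T47D are breast cancer lines, and a line labelled MCF-7-TNR is grouped with them as breast by its label. The labels do not spell out TNR, and no parental MCF-7 library was analysed here, so the origin of that line stays open. The cells grew in flat culture with serum, and total RNA was extracted near 80% confluence. The sample labels give no treatment, whereas the series' design text speaks of transfected cells, so the libraries are described here as the sample labels give them. Total expected counts per library, rounded to 5 digits, ran from 16454000 to 52053000, with a median of 37296000. They were 16454000 to 17718000 in A549, 29396000 to 42422000 in H23, 46008000 to 52053000 in MDA-MB-231, 41584000 to 42762000 in MCF-7-TNR and 25902000 to 31680000 in T47D.

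Libraries of 1 line resembled each other far more than those of different lines. Pearson's r of log2 CPM, which are counts scaled by library size, across genes, which are not independent replicates, was 0.979 to 0.997 within lines and averaged 0.725 to 0.826 between lines. The lowest mean was between MCF-7-TNR and T47D (0.725) and the highest between MCF-7-TNR and H23 (0.826). A549 averaged 0.812 with MDA-MB-231 and 0.803 with H23, so likeness between these lines did not follow the tissue label. MCF-7-TNR is of open origin, and the A549 libraries differed from the others in RNA classes, so this says little of tissue itself. The first 4 principal components held 31.5%, 27.3%, 21.7% and 15.8% of the variance. The labels do not say that the 3 libraries of a line came from separate cultures. The p-value of a gene between a pair of lines therefore measures the spread between these libraries, which may be technical. For lung and breast, tested on line sums, it measures the spread between lines. Camera with its preset correlation sets the members of a list against the other genes, and Fisher's exact test takes genes as its units.

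The levels of 12 genes chosen beforehand were set side by side in the 5 lines. CDKN2A, which encodes the cell cycle inhibitor p16, had no counts in A549 and 1 count in MDA-MB-231, against 19.97 ± 2.26 CPM in H23, 30.9 ± 11 in T47D and 93.6 ± 30.5 in MCF-7-TNR (mean ± SD, n = 3 libraries per line, here and below). MTAP, an enzyme of methionine salvage, had no counts in MDA-MB-231, 6.70 ± 0.808 CPM in A549 and 57.0 ± 8.84 CPM in MCF-7-TNR. ESR1, the estrogen receptor, reached 182 ± 10.3 CPM in T47D and stayed at or below 0.576 ± 0.205 CPM, the A549 level, in the other lines. PGR, the progesterone receptor, reached 573 ± 56.7 CPM in T47D and 7.28 ± 0.983 CPM in MCF-7-TNR. CDH1, which encodes E-cadherin, reached 431 ± 90.3 CPM in T47D, against 4.41 ± 2.72 in MCF-7-TNR and 1.65 ± 0.168 in MDA-MB-231. The intermediate filament gene VIM stood at 3.54 ± 0.384 CPM in T47D and 2993 ± 9.27 CPM in MDA-MB-231. NQO1, a quinone reductase, ranged from 3.31 ± 0.0727 CPM in MCF-7-TNR to 2521 ± 66.2 CPM in A549. CASP3, the executioner caspase, was detected in all 5 lines, at 52.2 ± 5.16 CPM in MCF-7-TNR. ERBB2 ran from 58.7 to 108 CPM across the lines and STK11 from 20.7 to 78.1 CPM. A count of 0 over a line allowed up to 0.0601 CPM in A549 and 0.0215 CPM in MDA-MB-231.

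**Figure D1:**
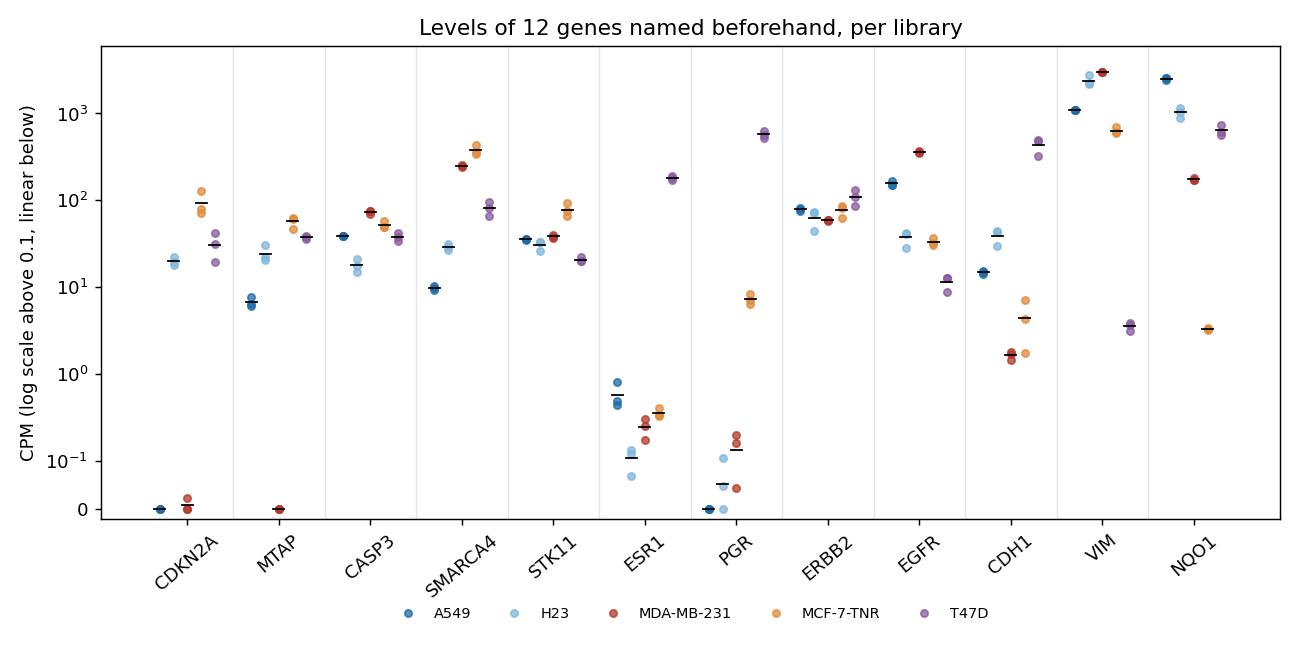
CPM of 12 genes, on an axis that is logarithmic above 0.1 and linear below it, with 1 point per library and a black bar at the mean of the 3 libraries of each line. ESR1 and PGR were highest in T47D, at means of 182 and 573 CPM, and CDKN2A was highest in MCF-7-TNR, at a mean of 93.6 CPM.

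A549 and H23 were compared to find how the 2 lung lines differ. A549 held far more transcript of 2 aldo-keto reductases: AKR1B10, which reduces aldehydes, stood at 4652 ± 166 against 0.227 ± 0.0663 CPM, and AKR1C2, another member of that family, at 3349 ± 68.7 against 0.102 ± 0.0432 CPM. ALDH1A1, which oxidises retinaldehyde, stood at 9334 ± 66.3 against 0.564 ± 0.215 CPM. H23 held MAGEA4, a cancer-testis antigen, at 469 ± 29.02 CPM, and CCND2, a D-type cyclin, at 217 ± 41.3 CPM, where A549 had 2 counts and 1 count. Of 17673 genes tested, 12819 differed, 6100 higher in A549 and 6719 lower, and 8875 of them differed by 2-fold or more, 4197 higher and 4678 lower. With upper-quartile factors 5510 were higher and 7400 lower.

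Among the most changed genes, HAVCR1, a surface receptor first known from injured kidney, had no counts in H23 and was at least 8364-fold higher in A549. The keratin gene KRT81 was higher by a log2 fold change of 14.41 ± 0.26 (estimate ± SE derived from the test), AKR1B10 by 14.34 ± 0.26 and AKR1C2 by 14.97 ± 0.48. KRT81, AKR1B10 and AKR1C2 had 10, 24 and 11 counts in H23, where such an SE can be too small. SCOC was at least 2774-fold higher, and the keratin pseudogene KRT87P at least 2264-fold higher. The metallothionein gene MT1E and the ligand gene WNT2 had no counts in A549 and were at least 1405-fold and 1084-fold lower there. MAGEA4 was 11765-fold (interval 3257 to 97152) lower in A549, and CCND2 was 10845-fold (interval 1946 to 428390) lower. EGR1, an immediate-early transcription factor, was 2504-fold (interval 857 to 12146) lower, and CDH11, a mesenchymal cadherin, 1781-fold (interval 493 to 14709) lower. NTSR1, LRP2, KCNQ2 and NPTX2, which encode a neurotensin receptor, an endocytic receptor, a potassium channel and a pentraxin, stood at 110.3, 73.3, 69.6 and 52.3 CPM in H23 and had 1 count each in A549. RMRP, SCARNA13, HIST1H3C and HIST1H4B completed the 20 genes, all 4 of them higher in A549. The AKR1C, KRT81, KRT87P, MT1 and histone genes have near-identical copies, so their values are uncertain. The largest adjusted p among the 20 was 3.25e-08, and by the rule that chose them none overlapped between the groups, a separation that chance gives for 10% of genes.

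Targets of NRF2, the transcription factor of the oxidative stress response, had the lowest p of the lists: 29 of 30 tested members were higher in A549, none lower and 1 not called, with a median log2 fold change of 2.97 (camera adjusted p = 5.47e-11; adjusted p = 0.136 with an estimated correlation). Of the replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 19 of 21 were higher, 1 lower and 1 not called (adjusted p = 9.85e-10; adjusted p = 0.00203 with an estimated correlation), and HIST1H3C was at least 3686-fold higher. In the list of structural and noncoding RNA, 7 of 10 were higher and 2 lower (adjusted p = 0.0308; adjusted p = 0.406 with an estimated correlation), with RMRP, the RNA of RNase MRP, at 9177 ± 562 against 0.267 ± 0.233 CPM and RPPH1, the RNA of RNase P, at 4089 ± 374 against 0.264 ± 0.281 CPM. RNA classes without a poly(A) tail took 2.37% ± 0.0348 of the counts in A549 and 0.0177% ± 0.00284 in H23, and mitochondrial rRNA took 0.0117% ± 0.00253 and 1.57% ± 0.564. Without those tail-less classes, an alternative chosen after seeing the data, the structural list had adjusted p = 0.859 and the histone list had no members left.

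Liver and gut secretory genes were mostly higher in A549, 14 of 19 against 1 lower, with a median of 4.87 (adjusted p = 0.000187; adjusted p = 0.191 with an estimated correlation). FGA, which encodes fibrinogen alpha, was at least 1162-fold higher, HNF4A, a hepatic transcription factor, was higher by 9.96 ± 0.33, and the intestinal factor CDX2 was lower at -4.20 ± 0.31. Basal breast genes were higher for 12 of 16 and lower for 3 (adjusted p = 0.0308; adjusted p = 0.138 with an estimated correlation), among them the laminin gene LAMB3 at 5.36 ± 0.28 and the forkhead gene FOXC1 at -4.34 ± 0.16. Drug efflux and detoxification genes were higher for 13 of 20 and lower for 5 (adjusted p = 0.0398; adjusted p = 0.191 with an estimated correlation), and cholesterol synthesis genes for 17 of 24 against 4 lower (adjusted p = 0.0308; adjusted p = 0.829 with an estimated correlation). MGST1, a membrane glutathione transferase, was higher by 6.65 ± 0.25, and MSMO1, a sterol oxidase, by 2.94 ± 0.22. Genes of MHC class I presentation went the other way, with 15 of 19 lower in A549 and 3 higher (adjusted p = 0.0308; adjusted p = 0.803 with an estimated correlation): HLA-B stood at 1.76 ± 0.322 against 399.6 ± 10.6 CPM.

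The other 18 lists did not pass the set test between the lung lines. Lung epithelial genes, with 6 of 16 higher and 4 lower, had adjusted p = 0.863. Reported deletions and losses had 4 of 10 higher and 4 lower, with adjusted p = 0.771, MTAP at -1.86 ± 0.17 and CASP3 at 1.12 ± 0.13. Hypoxia and glycolysis genes had 6 of 28 higher and 18 lower (adjusted p = 0.10), and H23 replicate 1 stood apart in them, with a median log2 ratio of -0.82 to the other 2 H23 libraries. Of markers of other cell types, 2 of 9 immune, 5 of 11 endothelial and 6 of 9 fibroblast markers were called (adjusted p = 0.771, 0.392 and 0.756). Adjusted over the list alone, called members numbered 20 rather than 21 of the interferon-stimulated list, 31 rather than 30 of the death receptor and apoptosis list, 21 rather than 20 of the histone list and 4 rather than 5 of the endothelial list, with the same numbers in the other 22. Without H23 replicate 1 the cholesterol synthesis and drug efflux lists each had adjusted p = 0.0566 and the hypoxia list, lower in A549, passed with 0.0380; without H23 replicate 3 the oxidative phosphorylation list, lower in A549, passed with 0.0476. Over 11 alternatives with camera the cholesterol list ran from 0.0140 to 0.829 and the drug efflux list from 0.0189 to 0.191.

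**Figure D2:**
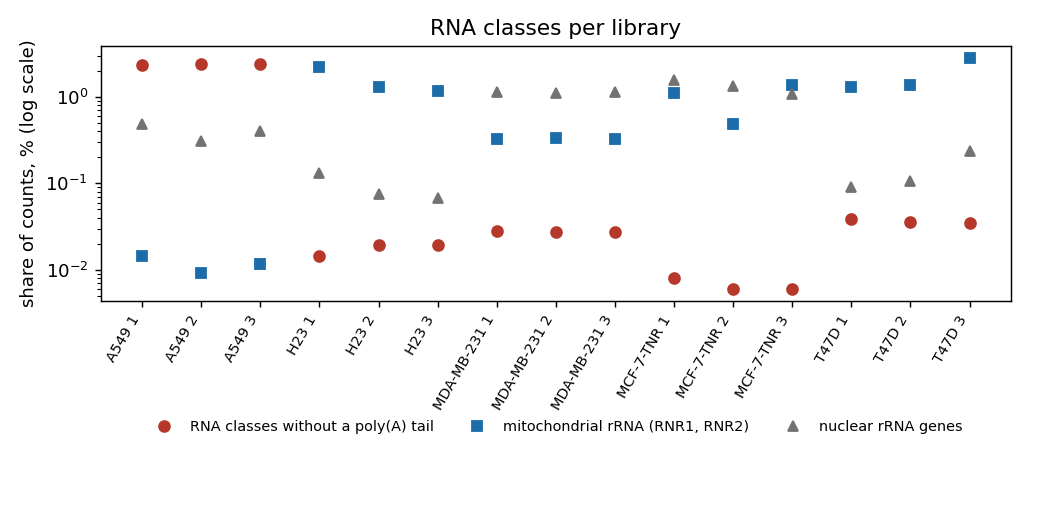
Share of counts, in percent on a logarithmic axis, taken by RNA classes without a poly(A) tail, by mitochondrial rRNA and by nuclear rRNA genes, with 1 point per class and library. The 3 A549 libraries had a mean of 2.37% tail-less RNA, against means of 0.00669% to 0.0363% in the other lines.

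MDA-MB-231 and T47D were compared as 2 breast lines. MDA-MB-231 held more transcript of mesenchymal genes: VIM stood at 2993 ± 9.27 against 3.54 ± 0.384 CPM, and MSN, which links membrane and actin, at 1399 ± 46.4 against 0.104 ± 0.0861 CPM. CAV1, the coat protein of caveolae and a member of the basal breast list, stood at 694 ± 17.2 CPM where T47D had 2 counts. T47D held more transcript of 3 genes known from breast epithelium: PRLR, the prolactin receptor, stood at 1831 ± 235 against 1.87 ± 0.123 CPM, MGP, a matrix protein, at 4726 ± 1359 against 0.160 ± 0.0790 CPM, and PGR at 573 ± 56.7 against 0.135 ± 0.0813 CPM. EGFR, the epidermal growth factor receptor, was higher in MDA-MB-231 by 4.96 ± 0.19, and CDH1 was lower at -8.03 ± 0.42. Of 17673 genes 13239 differed, 6748 higher in MDA-MB-231 and 6491 lower, and 9213 differed by 2-fold or more, 4535 higher and 4678 lower. With upper-quartile factors 5739 were higher and 7440 lower, with DESeq2 size factors 6500 and 6694, and with the DESeq2 Wald test 6501 and 6666.

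Genes with no counts in T47D included NRG1, a ligand of ERBB receptors, SLIT2, an axon guidance protein, and AOX1, an aldehyde oxidase, which were at least 3667-fold, 3572-fold and 4080.4-fold higher in MDA-MB-231. BCAT1, which transaminates branched-chain amino acids, the kinase gene RPS6KA3 and TNFRSF10D, a decoy receptor for TRAIL, were at least 3553-fold, 2989-fold and 2477-fold higher, and MAP7D3 and SPANXB1 at least 5035-fold and 4847-fold. CAV1 was 29563-fold (interval 8184 to 244120) higher. The secretory pathway gene AGR3, the NAD synthesis gene QPRT and LIN28A, which blocks let-7 maturation, had no counts in MDA-MB-231 and were at least 7237-fold, 6453-fold and 3722-fold lower. MGP was lower at a log2 fold change of -14.84 ± 0.42, SERPINA6, which carries corticosteroids in blood, at -14.54 ± 0.41, and PIP, the prolactin-induced protein, at -14.97 ± 0.90. PIP varied widely in T47D, at 1732 ± 1622 CPM. RAB25, OLFM1, KRT23 and CXCL12 had 1 count each in MDA-MB-231 and 213, 246, 229 and 214 CPM in T47D. CDH11 had 1 count in T47D and 372 ± 7.10 CPM in MDA-MB-231. The largest adjusted p among the 20 genes was 3.79e-09, and none overlapped between the libraries.

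Luminal identity genes were lower in MDA-MB-231 for 19 of 19 tested, with a median of -5.05 (adjusted p = 1.75e-09; adjusted p = 0.0167 with an estimated correlation). Epithelial junction genes were lower for 27 of 28, with 1 not called and a median of -3.76 (adjusted p = 1.75e-09; adjusted p = 0.0275 with an estimated correlation). Estrogen response genes were lower for 19 of 24 and higher for 4 (adjusted p = 3.72e-05; adjusted p = 0.0332 with an estimated correlation), with PGR lower at -12.01 ± 0.32 and the survival gene BCL2 higher by 5.66 ± 0.26. Basal breast genes were higher for 11 of 16 and lower for 2 (adjusted p = 0.00209; adjusted p = 0.0332 with an estimated correlation), with CDH3, P-cadherin, lower at -6.16 ± 0.22. Mesenchymal genes were higher for 24 of 27 and lower for 1, with a median of 7.04 (adjusted p = 1.09e-08; adjusted p = 0.0693 with an estimated correlation).

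NF-kappaB targets were higher in MDA-MB-231 for 26 of 30 and lower for 1 (adjusted p = 3.05e-08; adjusted p = 0.201 with an estimated correlation). The cytokine genes CSF2 and CXCL8 stood at 47.1 ± 3.23 and 408 ± 3.82 CPM there, against 0 and 0.0795 ± 0.0866 CPM in T47D. Interferon-stimulated genes were higher for 23 of 36 and lower for 4 (adjusted p = 0.00147; adjusted p = 0.486 with an estimated correlation), with IFIT3 higher by 6.67 ± 0.35 and BST2 lower at -1.41 ± 0.26. T47D replicate 3 stood apart in these lists: its median log2 ratio to the other 2 T47D libraries was 1.04 over the interferon-stimulated list, 0.78 over the NF-kappaB list and 0.65 over the hypoxia list, and its share of mitochondrial rRNA was 2.86%, against 1.29% and 1.37%. Death receptor and apoptosis genes were higher for 25 of 34 and lower for 7 (adjusted p = 0.00350; adjusted p = 0.0693 with an estimated correlation). Oxidative phosphorylation genes were lower for 22 of 27 with none higher (adjusted p = 5.73e-05; adjusted p = 0.376 with an estimated correlation), and NDUFA4, a respiratory chain subunit, was lower at -2.59 ± 0.15.

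The share of RNA without a poly(A) tail was 0.0274% in MDA-MB-231 and 0.0363% in T47D. Histone genes were lower for 12 of 21 and higher for 4, and cholesterol synthesis genes lower for 15 of 24 and higher for 3 (adjusted p = 0.0371 for each; adjusted p = 0.127 and 0.573 with an estimated correlation). Hypoxia and glycolysis genes were higher for 17 of 28 and lower for 3, and MHC class I genes higher for 11 of 19 and lower for 3 (adjusted p = 0.0436 for each; adjusted p = 0.651 and 0.486 with an estimated correlation), with SLC2A1, a glucose transporter, higher by 4.72 ± 0.26 and HLA-A by 3.11 ± 0.27. MHC class II genes were higher for 9 of 12 and lower for 2, and cell cycle genes higher for 18 of 30 and lower for 5 (adjusted p = 0.0482 for each; adjusted p = 0.486 and 0.125 with an estimated correlation). Of markers of other cell types, CD68, a macrophage marker, stood at 128 ± 9.10 against 1.44 ± 0.639 CPM, and 6 of 9 immune, 6 of 11 endothelial and 5 of 9 fibroblast markers were higher (adjusted p = 0.0686, 0.0532 and 0.149). Adjusted over the list alone, called members numbered 9 rather than 10 of the liver and gut list and 28 rather than 27 of the interferon-stimulated list. Without T47D replicate 2 the MHC class I, MHC class II, cholesterol and hypoxia lists each had adjusted p = 0.0676 and the cell cycle list 0.0658, without replicate 3 the cell cycle list had 0.0522 and HLA-F went from -1.54 ± 0.42 to -0.67 with adjusted p = 0.0502, and without replicate 1 the hypoxia list had 0.0509; with DESeq2 size factors the cell cycle list had 0.0516, and over 10 alternatives with camera the p of these 5 lists ran from 0.00507 to 0.651. The endothelial list passed with 0.0376 to 0.0488 without any 1 of the MDA-MB-231 libraries or of T47D replicates 1 and 3, with DESeq2 size factors (0.0483) and with no filter (0.0171).

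MCF-7-TNR and T47D were compared as a second pair of lines labelled breast. The MCF-7-TNR libraries held less of most luminal and epithelial transcripts than T47D: AGR2, a secretory pathway protein, stood at 0.0368 ± 0.0462 against 3340.4 ± 524 CPM, ESR1 at 0.354 ± 0.0422 against 182 ± 10.3 CPM, and ST14, an epithelial protease, at 0.0802 ± 0.0471 against 289 ± 36.1 CPM. They held transcripts without counts in T47D: IRS4, an insulin receptor substrate, stood at 550.1 ± 119 CPM, NEFL, the light neurofilament chain, at 249 ± 31.4 CPM, and SOX11, a transcription factor of neural progenitors, at 164 ± 35.7 CPM. Of 17673 genes 13245 differed, 6953 higher in MCF-7-TNR and 6292 lower, and 9242 differed by 2-fold or more, 4897 higher and 4345 lower. Upper-quartile factors gave 6718 higher and 6525 lower.

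IRS4, SLIT2 and NEFL were at least 15563-fold, 13116-fold and 7042-fold higher in MCF-7-TNR. The inner ear protein gene COCH, SOX11 and the amino acid transporter gene SLC6A15 were at least 4931-fold, 4658-fold and 4220.5-fold higher, and DPYSL5, DZIP1, BCAT1 and the retinoic acid synthesis gene ALDH1A2 at least 3404-fold, 3176-fold, 2991-fold and 2945-fold. AGR2 was lower at -16.36 ± 0.35. KRT23, AGR3, TFF3, a mucosal trefoil peptide, and ELF5, a transcription factor of mammary alveolar cells, had no counts in MCF-7-TNR and were at least 10648-fold, 7166-fold, 7063-fold and 6067-fold lower. SPINK5 and RHOD were at least 4388-fold and 3554-fold lower. MGP and SERPINA6 had 3 counts each in MCF-7-TNR, and PIP had 2. CDKN2A was higher by 1.60 ± 0.26, SMARCA4, the ATPase of a chromatin remodeller, by 2.24 ± 0.13, and VIM by 7.49 ± 0.14, while NQO1 was lower at -7.59 ± 0.15. The largest adjusted p among the 20 most changed genes was 2.08e-07, and none overlapped between the libraries.

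Epithelial junction genes were lower in MCF-7-TNR for 27 of 28, with a median of -6.83 (adjusted p = 2.92e-11; adjusted p = 0.0147 with an estimated correlation), and luminal identity genes for 19 of 19, with a median of -7.42 (adjusted p = 8.30e-11; adjusted p = 0.0101 with an estimated correlation). Estrogen response genes were lower for 20 of 24 and higher for 3 (adjusted p = 4.58e-05; adjusted p = 0.0440 with an estimated correlation), with CXCL12 lower at -12.39 ± 0.33 and ELOVL2, a fatty acid elongase, higher by 1.79 ± 0.14. Mesenchymal genes were higher for 23 of 27 and lower for 2, with a median of 5.63 (adjusted p = 2.84e-06; adjusted p = 0.137 with an estimated correlation), and MSN was higher by 11.01 ± 0.29. Neuroendocrine genes were higher for 14 of 17 and lower for 1, with a median of 2.54 (adjusted p = 0.000589; adjusted p = 0.0571 with an estimated correlation), and NCAM1, a neural adhesion molecule, was 1643-fold (interval 562 to 7967) higher.

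Interferon-stimulated genes were lower in MCF-7-TNR for 23 of 36 and higher for 7 (adjusted p = 0.00778; adjusted p = 0.748 with an estimated correlation), with OAS3 lower at -7.62 ± 0.33 and LGALS3BP higher by 2.79 ± 0.22. T47D replicate 3 held more of this list than the other 2 T47D libraries, at a median log2 ratio of 1.04. MHC class I genes were lower for 13 of 19 and higher for 3 (adjusted p = 0.00998; adjusted p = 0.514 with an estimated correlation), with the immunoproteasome gene PSMB8 lower at -9.23 ± 0.43 and HLA-A higher by 1.73 ± 0.25. MHC class II genes were higher for 4 of 12 and lower for 4 (adjusted p = 0.901). Oxidative phosphorylation genes were lower for 19 of 27 and higher for 3 (adjusted p = 0.000914; adjusted p = 0.511 with an estimated correlation), histone genes lower for 14 of 21 with none higher (adjusted p = 0.00586; adjusted p = 0.0579 with an estimated correlation) at tail-less RNA shares of 0.00669% in MCF-7-TNR and 0.0363% in T47D, and cancer-testis antigens lower for 10 of 15 and higher for 1 (adjusted p = 0.00778; adjusted p = 0.481 with an estimated correlation). Fibroblast markers were higher for 6 of 9 and lower for 1 (adjusted p = 0.0501), and passed with 0.0496 and 0.0430 without MCF-7-TNR replicates 2 and 3, 0.0480 with DESeq2 size factors and 0.0469 with a replicate block. With no filter the structural RNA list passed as lower with 0.0421. Adjusted over the list alone, called members numbered 10 rather than 11 in the liver and gut list and in the cancer-testis list. ERBB2, with a log2 fold change of -0.50 ± 0.18 and adjusted p = 0.0217, had adjusted p = 0.105 without MCF-7-TNR replicate 3 and 0.131 without T47D replicate 1; IL32, at 1.68 ± 0.62 and 0.0220, had 0.0564 without MCF-7-TNR replicate 1, 0.0607 and 0.0724 without T47D replicates 1 and 2, and 0.0638 in a fit of the 6 libraries alone.

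MDA-MB-231 and MCF-7-TNR, both low in luminal transcripts, were compared with each other. MDA-MB-231 held more transcript of basal breast genes and of CD74: LAMC2 and LAMB3, 2 chains of the epithelial laminin, stood at 411 ± 1.79 and 462 ± 10.8 CPM against 0.444 ± 0.215 and 0.864 ± 0.359 CPM, and CD74, the chaperone of MHC class II, at 215 ± 16.9 against 0.861 ± 1.14 CPM. MCF-7-TNR held UCHL1, a neuronal ubiquitin hydrolase, at 338 ± 43.1 CPM, LIN28B at 142 ± 21.3 CPM and HOXA9, a body axis gene, at 134 ± 23.18 CPM, each with no counts in MDA-MB-231. EGFR was higher in MDA-MB-231 by 3.44 ± 0.17 and VIM by 2.23 ± 0.11, while PGR was lower at -5.71 ± 0.30. Of 17673 genes 12571 differed, 6032 higher in MDA-MB-231 and 6539 lower, and 8065 differed by 2-fold or more, 3679 higher and 4386 lower. Upper-quartile factors gave 5200 higher and 7415 lower.

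IRS4, UCHL1, SOX11 and LIN28B were at least 25528-fold, 15698-fold, 7640.4-fold and 6630.2-fold lower in MDA-MB-231. HOXA9, DPYSL5, CBS, which makes cystathionine, ZNF711 and CNTNAP2 were at least 6249-fold, 5584-fold, 5330.5-fold, 4686-fold and 3866-fold lower, and NEFL had 1 count in MDA-MB-231. In the other direction TM4SF1, a membrane protein, was higher in MDA-MB-231 by 11.85 ± 0.41, SRGN, a granule proteoglycan, by 11.49 ± 0.50 and EVI2B by 11.36 ± 0.27. The cytokine gene IL1B was 4570.3-fold (interval 1265 to 37744) higher and the EGFR ligand gene EREG 3732-fold (interval 1277 to 18100) higher. UCA1, a long noncoding RNA, was 4446-fold (interval 1521 to 21561) higher and the protease inhibitor gene SERPINB9 4482-fold (interval 1240.3 to 37013) higher. C4BPB, KRT81 and SLCO1B3 had 1 count each in MCF-7-TNR and 86.0, 75.3 and 68.6 CPM in MDA-MB-231. The largest adjusted p among the 20 genes was 9.58e-10, and none overlapped between the libraries.

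NF-kappaB targets were higher in MDA-MB-231 for 29 of 30, with none lower and a median of 4.66 (adjusted p = 7.12e-10; adjusted p = 0.226 with an estimated correlation). Interferon-stimulated genes were higher for 33 of 36 and lower for 2, with a median of 3.85 (adjusted p = 9.67e-09; adjusted p = 0.394 with an estimated correlation), and XAF1 was at least 392-fold higher. MHC class I genes were higher for 17 of 19 and lower for 1 (adjusted p = 8.23e-06; adjusted p = 0.255 with an estimated correlation), with PSMB8 higher by 9.82 ± 0.43 and HLA-F lower at -1.93 ± 0.41. Basal breast genes were higher for 14 of 16 and lower for 1 (adjusted p = 1.75e-05; adjusted p = 0.0133 with an estimated correlation), with FOXC1 lower at -2.62 ± 0.13. Death receptor and apoptosis genes were higher for 23 of 34 and lower for 3 (adjusted p = 0.000176; adjusted p = 0.0527 with an estimated correlation), with MLKL, the effector of necroptosis, higher by 8.17 ± 0.26. Neuroendocrine genes were lower for 12 of 17 and higher for 1 (adjusted p = 0.000655; adjusted p = 0.0842 with an estimated correlation). Cancer-testis antigens were higher for 9 of 15 and lower for 1 (adjusted p = 0.0121; adjusted p = 0.483 with an estimated correlation), with SPANXB1 higher by 11.28 ± 0.39. Immune cell markers were higher for 6 of 9 (adjusted p = 0.0601), with CD68 higher by 4.99 ± 0.25. Adjusted over the list alone, called members numbered 14 rather than 16 in the cholesterol list and 9 rather than 8 in the fibroblast list. Without MCF-7-TNR replicate 3 the cancer-testis list had adjusted p = 0.0577, with a range of 0.0101 to 0.483 over 10 alternatives with camera. Without MCF-7-TNR replicate 1 the mesenchymal and MHC class II lists, each higher in MDA-MB-231, passed with 0.0378 each, and with no filter the mesenchymal and cell cycle lists, higher there too, passed with 0.0335 each.

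**Figure D3:**
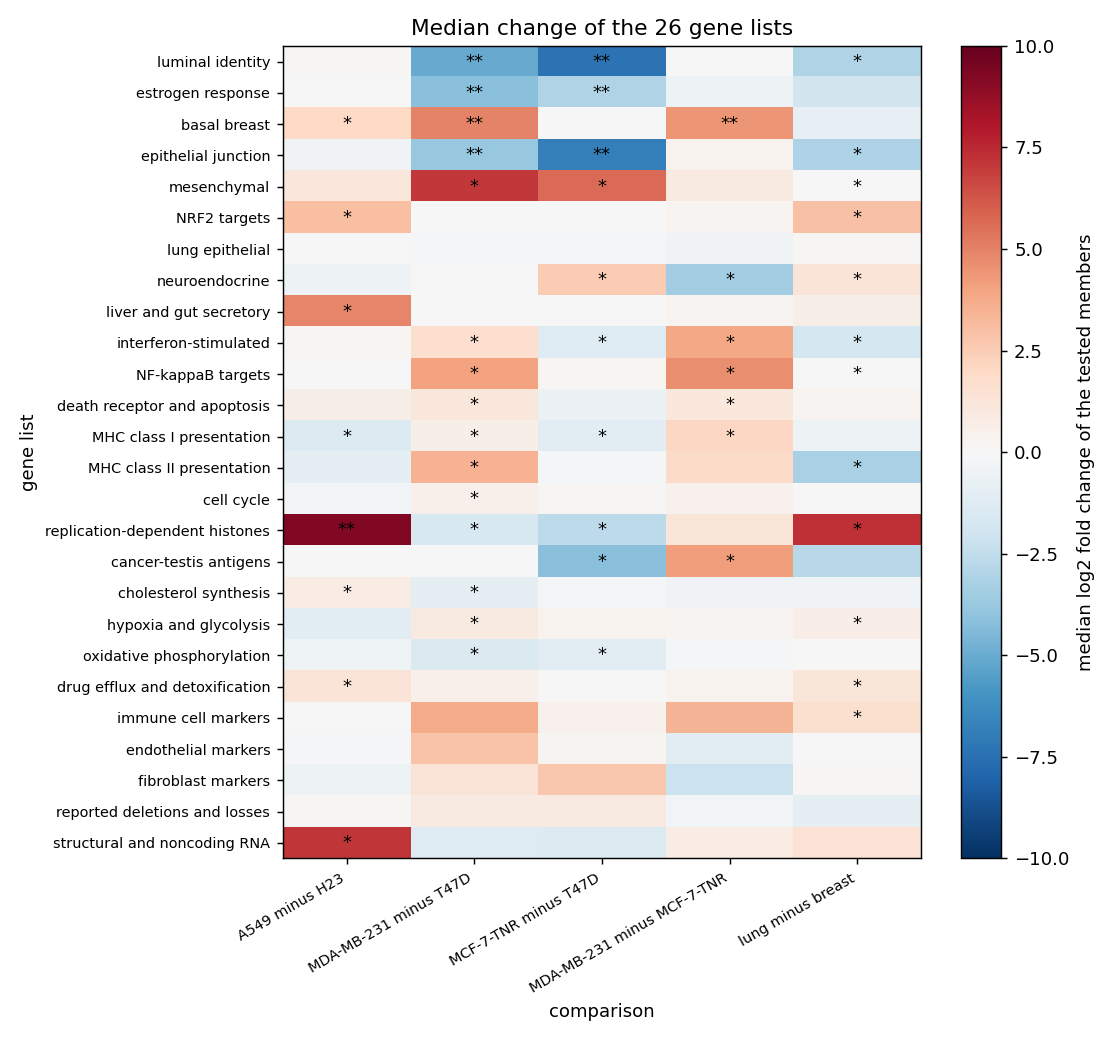
Median log2 fold change of the tested members of 26 gene lists, on a colour scale, for the 5 comparisons, with genes at 0 counts in a group placed at their bound. An asterisk marks adjusted p under 0.05 in camera with its preset correlation, and 2 asterisks mark lists that also passed with an estimated correlation; luminal identity was at -5.05 in MDA-MB-231 and -7.42 in MCF-7-TNR against T47D.

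The lung and breast lines were compared with the line as the replicate, 2 lung lines against 3 lines labelled breast. MCF-7-TNR is among the latter, although its origin stays open. NQO1 stood at 1786 ± 1081 CPM in the lung lines and 275 ± 331 CPM in the breast lines, and SMARCA4 at 19.3 ± 13.5 and 238 ± 149 CPM, where the SD is between lines. Their log2 fold changes were 2.70 ± 1.64 and -3.62 ± 0.96, with adjusted p of 0.961 for each. By the DESeq2 Wald test SMARCA4 had a log2 fold change of -3.59 with adjusted p = 0.0180. CDH1 ran from 14.8 to 39.1 CPM across the lung lines and from 1.65 to 431 CPM across the breast lines, with a log2 fold change of -2.44 ± 2.26, and VIM had 0.49 ± 1.86. None of 17536 genes was called by edgeR's quasi-likelihood test, while 809 had an unadjusted p under 0.05 (470 to 1224 in the 9 other splits of the lines, with 6 of them above 809), DESeq2 called 429 and limma-voom with the line as a random block called 8.

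NRF2 targets were higher in the lung lines, with a median of 2.89 over 29 tested members (adjusted p = 6.75e-11; adjusted p = 0.756 with an estimated correlation and 0.805 with fry), none called over all genes and 10 adjusted over the list alone. Histone genes had a median of 7.33 over 18 members (adjusted p = 3.75e-06; 0.756 with an estimated correlation), 11 of them called when adjusted over the list alone, and the tail-less RNA share was 2.37% in A549 against 0.0177% in H23. MHC class II genes were lower in the lung lines, with a median of -3.21 (adjusted p = 8.43e-05; 0.756 with an estimated correlation). Epithelial junction genes were lower at a median of -3.09, interferon-stimulated genes lower at -1.72 and hypoxia genes higher at 0.69 (adjusted p = 0.00185 for each; 0.756 with an estimated correlation). Neuroendocrine genes were higher at a median of 1.25 (adjusted p = 0.00199), drug efflux genes at 1.23 and immune markers at 1.59 (adjusted p = 0.00907 for each), and luminal identity genes lower at -3.04 (adjusted p = 0.0391), each at 0.756 with an estimated correlation. Mesenchymal genes and NF-kappaB targets passed as higher (adjusted p = 0.0324 and 0.0229) although their medians were 0.01 and -0.07 and their means -0.06 and -0.01. All 12 of these lists had adjusted p = 0.756 with an estimated correlation and 0.805 with fry. Adjusted over the list alone, 1 immune marker and 4 structural RNA genes were called, and none in the other 22 lists. Among lists not past the test, median, mean and test differed in sign for the basal breast, lung epithelial, cell cycle, cancer-testis, oxidative phosphorylation, endothelial and fibroblast lists here; for the lung epithelial, NF-kappaB, cancer-testis and deletions lists between the lung lines; for the NRF2, lung epithelial, cancer-testis and deletions lists between MDA-MB-231 and T47D; for the lung epithelial, NF-kappaB and MHC class II lists between MCF-7-TNR and T47D; and for the histone and endothelial lists between MDA-MB-231 and MCF-7-TNR.

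Leaving out a line, chosen after seeing the data for the lists, ended many of these calls: without A549, NRF2 targets had adjusted p = 0.064, histone genes 0.705, mesenchymal genes 0.307, drug efflux genes 0.218, immune markers 0.191, NF-kappaB targets 0.101, luminal genes 0.0791 and junction genes 0.0671. Without H23, neuroendocrine genes had 0.19, interferon-stimulated genes 0.211, luminal genes 0.223, NF-kappaB targets 0.187, hypoxia genes 0.295 and immune markers 0.486, without MDA-MB-231 interferon-stimulated genes had 0.585, without MCF-7-TNR NF-kappaB targets had 0.576 and drug efflux genes 0.062, and without T47D luminal genes had 0.998, junction genes 0.88, mesenchymal genes 0.283, NF-kappaB targets 0.47 and immune markers 0.1, with the luminal and mesenchymal directions turned. Immune markers could not be tested without MCF-7-TNR, and with no filter on low counts they had 0.253. Lists gained calls too: without H23 the liver and gut (1.54e-09) and structural RNA (1.43e-07) lists, without MDA-MB-231 the estrogen (0.00477), death receptor (0.00115) and cancer-testis (0.0313) lists, without MCF-7-TNR the estrogen (0.0286) and fibroblast (0.0129) lists, and without T47D the cancer-testis (0.0430), oxidative phosphorylation (0.00557) and structural RNA (0.0299) lists. With no filter and all 5 lines the liver and gut list passed with 0.00201.

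Genes that set a single line apart, at least 4-fold higher there than in each of the other 4 lines, numbered 2863. The genes said to lead a line are those at 50 CPM or more there, ranked by their smallest fold change against another line. T47D had 829, led by PIP, MGP, KRT23, AGR3, ELF5, FXYD3, SERPINA6 and CXCL12; MGP stood at 4726 ± 1359 CPM, and the highest mean of another line was 0.160 CPM. MCF-7-TNR had 624, led by IRS4, PDPN, HOXD13, ALDH1A2, SOX11, NCAM1, HEY1, a Notch target, and HOXA9, with PDPN, a lymphatic and mesothelial glycoprotein, at 52.6 ± 0.654 CPM. A549 had 544, of which 127 encode RNA classes without a poly(A) tail and 417 do not. The 544 were led by AKR1B10, ALDH1A1, RMRP, CPLX2, RPPH1, HIST1H4B, AKR1C2 and HIST2H2AB. Whether a difference in library preparation also touched some of the 417 cannot be told apart from the line. MDA-MB-231 had 484, led by the cystatin genes CST1 and CST4, SLC17A9, ADGRF5, ACSL5, EVI2B, TLR4 and COL8A1, with TLR4, a receptor for bacterial lipopolysaccharide, at 99.5 ± 2.68 CPM. H23 had 382, led by MAGEA4, SPOCK2, NTSR1, the chemokine gene CCL20, BCL6B, WNT2, DUSP2 and MAGEA3, with SPOCK2 at 1079 ± 389 CPM.

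The fixed lists were unevenly spread over these genes by Fisher's exact test, one-sided and adjusted over 130 list and line pairs. The test takes list members as independent, so its p-values are too small where members move together. A549 held 18 of 21 histone genes (adjusted p = 7.41e-23), 17 of 30 NRF2 targets (8.4e-17), 10 of 19 liver and gut secretory genes (1.32e-09), 5 of 10 structural and noncoding RNA genes (7.19e-05) and 4 of 20 drug efflux genes (0.0236). T47D held 16 of 28 epithelial junction genes (3.71e-13), 13 of 19 luminal identity genes (3.3e-12), 9 of 24 estrogen response genes (1.35e-05) and 4 of 15 cancer-testis antigens (0.0331). MDA-MB-231 held 10 of 36 interferon-stimulated genes (6.29e-07), 8 of 30 NF-kappaB targets (1.67e-05), 5 of 9 immune cell markers (2.51e-05), 5 of 11 endothelial markers (7.19e-05), 5 of 15 cancer-testis antigens (0.000391), 4 of 12 MHC class II genes (0.00231) and 4 of 16 basal breast genes (0.00674). H23 held 4 of 17 neuroendocrine genes (0.0038). The A549 histone and structural RNA counts stood beside a tail-less RNA share of 2.37% there. In MCF-7-TNR the lowest adjusted p was 0.149, for 3 of 17 neuroendocrine genes.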

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

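Leaving out RNA classes without a poly(A) tail, leaving out a line for the list and line-specific counts, and the comparisons drawn from them were chosen after seeing the data. Counts of genes called between 2 lines stayed within 1.5 times under every alternative run: 11899 to 13119 for A549 and H23, 12620 to 13942 for MDA-MB-231 and T47D, 12046 to 13904 for MCF-7-TNR and T47D, and 11759 to 13162 for MDA-MB-231 and MCF-7-TNR. Leaving out each library gave 12093 to 13088, 12620 to 13060, 12789 to 13240 and 11759 to 12165 genes, and 7 to 9, 10 to 16, 10 to 11 and 6 to 9 lists; leaving out a replicate number from all 5 lines gave 2879 to 2921 line-specific genes and 0 genes between tissues. Lists past the test numbered 8, 15, 10, 7 and 12 (tissue last). With an estimated correlation they numbered 1, 4, 3, 1 and 0, and with fry 23, 25, 23, 23 and 0; without A549 the tissue comparison had 4. Line-specific genes numbered 5682 at a 2-fold threshold. Between tissues, 0 genes became 12385 in the contrast over 15 libraries, 12155 in that contrast with a replicate block, 429 with DESeq2 and 8 with limma-voom and the line as a random block. The 15-library contrasts replace the spread between lines by that between libraries of a line; the cause of the other moves was not tested. Replicate numbers did not pair the libraries, since deviations of same-numbered libraries correlated between -0.207 and 0.0588 over 30 pairs; with a replicate block the pairs of lines had 12547, 12981, 12996 and 12281 genes, 8, 15, 11 and 7 lists, and 2866 line-specific genes. Upper-quartile factors shifted the median log2 fold change of all genes by -0.16 for A549 and H23, -0.24 for MDA-MB-231 and T47D and -0.18 for MDA-MB-231 and MCF-7-TNR. Of 7143 values of named genes under alternatives, 7096 kept direction and side of the threshold, 7 lost the call, 23 gained it and 17 turned direction, all 17 between tissues. Most of these genes were named because they were called with large fold changes, which favours keeping the call, so the share says little of other genes. MTAP turned to 2.69 in the 15-library contrast, 2.69 with its replicate block and 2.89 with limma-voom; EGFR to 0.57, 0.57 and 0.42, and to 0.20 without H23 and 2.14 without MDA-MB-231; CDH1 to 0.72, 0.76 and 1.48, and to 3.15 without T47D. STK11 turned to 0.14 without MCF-7-TNR, ESR1 to 0.20 and ERBB2 to 0.066 without T47D, and VIM to -0.16 without H23 and -0.089 without T47D; the cause was not tested. Depth limits genes with few counts: A549, with totals of 16454000 to 17718000, has the highest floor, 0.0601 CPM.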

Other observations

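ABCB1, the efflux pump P-glycoprotein, stood at 41.2 ± 3.90 CPM in MCF-7-TNR, 0.805 ± 0.168 CPM in H23 and 0 in A549, and was 1913-fold (interval 654 to 9281) lower in MDA-MB-231 than in MCF-7-TNR. GSTP1, a glutathione transferase, ranged from 0.135 ± 0.133 CPM in T47D to 1649 ± 295 CPM in H23, and ABCC4, an exporter of cyclic nucleotides, had no counts in T47D and 182 ± 3.45 CPM in A549. TNFRSF10D, a decoy receptor for TRAIL, had no counts in T47D and 124 ± 26.5 CPM in H23. TNFRSF10A, a TRAIL receptor that signals death, was lower in MCF-7-TNR than in T47D at a log2 fold change of -4.04 ± 0.25, and MLKL at -6.47 ± 0.26, while the death receptor and apoptosis list did not pass between these lines (adjusted p = 0.354).

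The tests on S phase in A549 and the 3 tests on the origin of the MCF-7-TNR libraries were chosen only after the result was seen. Grouping the 6 libraries of 2 lines in other ways gave at most 1, 0, 0 and 0 genes, against 12819 (A549 and H23), 13239, 13245 and 12571 (MDA-MB-231 and MCF-7-TNR); 10 splits are too few for a share under 0.05, and in each comparison 1 of 10 gave as many genes as the real split. For tissue, all 10 splits of the 5 lines gave 0 genes, the real one included, and are likewise too few. Of 40 groupings of the 15 libraries into 5 groups of 3, only the real one, counted as 1, gave as many line-specific genes. The highest other had 517 against 2863. Random groupings mix lines, whose libraries are less alike, so the real grouping was bound to give the most. The comparison therefore cannot tell whether chance between cultures of a line gave it these genes.

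The A549 libraries held 2.37% of counts in histone, RNase P, RNase MRP, 7SL and small nucleolar RNA, against at most 0.0363% on average in the other lines. More cells in S phase would raise cell cycle genes, and the cell cycle list had a median log2 fold change of -0.058 in A549 against the other 4 lines (quartiles -0.56 and 0.21), which argues against it. Tail-less histone genes lay 10.18 above histone genes with a poly(A) tail (medians 9.97 and -0.20, over 21 and 9 genes), which is consistent with tail-less RNA having been kept in the A549 libraries and lost in the others. The labels give a single kit for all 15 libraries, so a difference in library preparation is a hypothesis, confounded with the line. Such a difference could also touch genes outside these classes, which bears on every comparison that holds A549. A property of the A549 cells other than the share in S phase was not tested and stays open.

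The MCF-7-TNR libraries held less luminal transcript than T47D, with 19 of 19 genes lower, and held CDKN2A and MTAP. RNA of another line of the series would give at most that line's level, but CDKN2A stood 3.03 times above the next highest line (2.34 times in the lowest library), which argues against it as the whole source. Exchanged labels need another line with ESR1 at 10 CPM or more and CDKN2A and MTAP under 1 CPM, and 0 such lines were found; that profile is assumed, so an exchange with a sample outside the series stays open. An MCF-7 derivative that changed state cannot be told apart from another origin: CDKN2A was at 93.6 CPM (lowest library 72.2), but no parental MCF-7 library was analysed here. What the label TNR stands for is not given, so no biological explanation was tested further.

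T47D replicate 3 held more interferon-stimulated and NF-kappaB target transcripts than replicates 1 and 2: 20 of 36 and 13 of 30 members were at least 2-fold higher, with medians of 1.04 and 0.78. RNA of another line would need a share of at least 12.5%, from MDA-MB-231, while genes specific to the other lines showed at most 0.272% of any line in this library, which argues against it. After removing a trend on GC content and length the median over 66 genes was 0.78, from 0.97 before; the share kept, 0.803 with an interval of 0.741 to 1.09, spans the bound of 0.8 set beforehand, so a part in such a trend cannot be told apart. No biological explanation was tested, since the design names no difference between these libraries. Cell cycle genes had a median of 0.00 in it, and hypoxia genes 0.65.

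H23 replicate 1 had a median log2 ratio of -0.82 over hypoxia and glycolysis genes, with 8 of 28 at least 2-fold lower than in the other 2 H23 libraries, and its log2 ratios across genes had a Spearman correlation of -0.526 with GC content.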
